A study of Rattus norvegicus with 9 samples.

How the data were processed

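RNA sequencing was done on brain tissue of rats in 3 groups of 3 samples each: rats that had a sham operation (sham), rats with middle cerebral artery occlusion (MCAO) and rats with the occlusion that received Panax notoginseng (PN). Per the labels' protocols, total RNA was extracted with Trizol, mRNA was enriched on oligo(dT) beads, fragmented and copied with random primers, and the libraries were sequenced on an Illumina HiSeq instrument. Groups were taken from the sample titles, and each library is called here by its group and the code that ends its title, such as MCAO 3B. The brain region, the hemisphere, the time of sampling, the strain and the dose are not given in the sources used here. Nothing in the labels says that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may in part be technical.

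The authors deposited 1 table of FPKM values (fragment numbers scaled to the length of the transcript and the number of mapped fragments), per the file headers, with 32883 rat Ensembl gene IDs and 9 sample columns. The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, HISAT2 and StringTie 1.3.1 without their roles. The genome build, the annotation release and the strand setting are not given in the sources used here. In 4792 rows the deposited FPKM had more than 6 decimals. The table lists 10541 genes at 0 in every library. Columns were matched to samples by the codes that end their names. The code 7A ends 2 titles, so its 2 columns were matched by the start of the name that they share with columns already matched. The column names start in ways that no label explains, with 2 different starts in the sham group and 2 in the PN group. The columns that start unlike the others of their group are those of PN 3A and sham 9A.

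The IDs could not be turned into gene names: the file gives only IDs, and the rat gene table used here (assembly GRCr8) paired 0 of them with a symbol. The 43 gene lists (cell types, stress, inflammation, metabolism) and the rule for named genes, both fixed before the data were examined, therefore could not be applied. At most 2 IDs that were higher and 2 that were lower are printed: the 3 genes that passed the test and 1 chosen after its values were seen. No genomic position is given for them.

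FPKM does not keep the number of reads, so no counting interval is given. The relative depth of the libraries was read from the steps of low values: between MCAO 3B and each other library, the ratios of values under 0.15 FPKM pile up at 1 ratio, that of genes with equal read numbers. Checked over pairs of other libraries, these ratios closed to within 2.86e-05 on the log2 scale. Read numbers per gene need the gene's length and were not recovered.

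Genes were tested when FPKM was at least 1 in at least 3 of the 9 libraries, which left 15051 genes. Values were used as deposited, on the log2(FPKM + 1) scale, so fold changes on this scale understate the change of low genes. All 9 libraries entered 1 limma fit of group means with a mean-variance trend (limma 3.58.1 in R 4.3.3), and the 3 comparisons were MCAO against sham, PN against MCAO and PN against sham. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Permutation tests were run in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. An FPKM of exactly 0 in such a table can be a failed estimate: between 8 and 17 genes per library were listed at 0 although their median over the 9 libraries was at least 5 FPKM. Such genes are given by their value in each library, without a mean or a fold.

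The pipeline was tested on simulated data, with gene means and spreads from these libraries and 200 of 15051 genes changed. For MCAO against sham it recovered 38.6% of genes changed 2-fold, 89.6% of those changed 4-fold and 97.2% of those changed 8-fold, and 4.97% of its calls were false. For PN against MCAO it recovered 37.8%, 92.2% and 99.0% at the same folds, with 4.95% false calls. For PN against sham the shares were 40.2%, 91.0% and 98.2%, with 5.15% false calls.

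Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter or a minimum of 5 FPKM, 3 other scalings of the libraries (equal sums, median of ratios, quantiles), robust empirical Bayes, array weights, a fit of only the 6 libraries compared, a fold of at least 2, the letter of the sample code as a covariate, the number of the sample code as a block, and each library left out in turn. Leaving out genes listed at 0 in any library, and array weights without PN 7A, were added after the data were seen. The codes of MCAO and PN share the numbers 3, 6 and 7, and the labels do not say that a number marks an animal, litter or day.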

Results

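The transcriptome of rat brain tissue was measured in 9 libraries, 3 each from sham-operated rats, from rats with middle cerebral artery occlusion (MCAO, a surgical model of ischaemic stroke) and from rats with the occlusion that were treated with Panax notoginseng (PN), a medicinal plant whose root is rich in saponins. The series is about cerebral ischaemia followed by reperfusion. Between 18239 genes (MCAO 6B) and 18928 genes (PN 6A) were listed above 0, and between 13934 (sham 5B) and 14687 (PN 6A) reached 1 FPKM. The sum of FPKM ranged from 387893 in MCAO 7A to 445693 in PN 3A. The 50 most abundant genes took 11.1% of it in sham 5B and 13.9% in MCAO 3B, at the 2 ends of the range. The absolute depth is unknown. The steps of low values put the deepest library, PN 7A, at 1.33 times the depth of MCAO 3B, the shallowest. The table identifies genes by Ensembl ID only, so genes are described here by number, direction and level, not by name or function.

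Most libraries were not closest to one of their own group, and none of the first 3 principal components separated all 3 groups. Over the 15051 genes tested, 2 of the 9 libraries correlated best with a library of their own group: MCAO 6B with MCAO 3B and sham 5B with sham 9A. The closest pair was PN 7A and sham 9A (Pearson r across genes of log2(FPKM + 1) = 0.9688), and the next closest was MCAO 7A and PN 6A (r = 0.9611). The mean r was 0.9349 over the 9 pairs within groups and 0.9265 over the 27 pairs between groups. Group means accounted for 31.5% of the variation, against a median of 24.3% over the 280 ways to part the 9 libraries into 3 sets of 3, and 39 of these ways gave as much (exact permutation p = 0.139, one-sided, a test chosen after the data were seen). The first component held 32.1% of the variation and had PN 3A and sham 4B at one end and MCAO 7A, PN 6A and MCAO 3B at the other. On it all MCAO libraries scored below all sham libraries, and the PN libraries spread across both. The second component (20.3%) set the PN libraries, from 3.72 to 35.1, above the sham libraries, from -51.75 to -3.13, with the MCAO libraries across both. Groups held 48.5% of the second component (40 of 280 partitions as large, exact permutation p = 0.143, one-sided) and 43% of the third (52 partitions, exact permutation p = 0.186, one-sided).

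**Figure D1:**
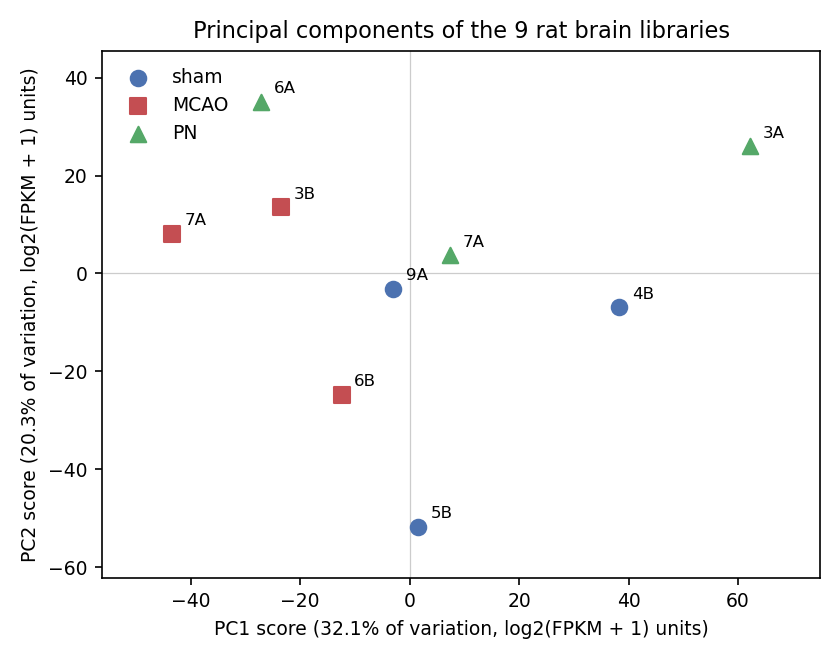
Scores of the 9 libraries on the first (x axis, 32.1% of variation) and second (y axis, 20.3%) principal components of centred log2(FPKM + 1), in log2 units; each point is 1 library, coloured and shaped by group and marked with its sample code. The 3 PN libraries lie far apart on the first component, from -27.2 to 62.2, and the 3 sham libraries on the second, from -51.7 to -3.13.

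MCAO was compared with sham to ask what the occlusion changed. Of the 15051 genes, 1 was lower in MCAO at an adjusted p under the threshold and none was higher. This gene, ENSRNOG00000054459, was at 22.9, 28.7 and 24.7 FPKM in sham 4B, 5B and 9A and was listed at 0 in all 3 MCAO and all 3 PN libraries (limma, adjusted p = 1.12e-05). Next in rank was ENSRNOG00000056374, at 12.8 ± 1.46 FPKM in sham and 2.32 ± 0.934 FPKM in MCAO (SD, n = 3 each), a log2 difference of -2.09 with a standard error of 0.26, lower in 3 of 3 MCAO libraries than in any sham library; it did not pass (limma, adjusted p = 0.121).

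Below that threshold the MCAO and sham libraries differed a little in many genes, but chance stays open as the source. At an unadjusted p under 0.05 there were 1673 genes (11.1%), of which 733 were higher and 940 lower in MCAO. Chance would give 753 on average. Genes vary together, so the count by chance scatters widely: other splits of the same libraries, each mixing the groups, gave 309 to 1414 genes. All 3 MCAO libraries lay above all 3 sham libraries in 1293 genes and below them in 1662, together 19.6% of the genes where chance gives 10%. Changes of at least 2-fold with no overlap numbered 138 higher and 193 lower. The split by direction depended on scaling and on single libraries: of the genes at an unadjusted p under 0.05, 43.8% were higher in MCAO as deposited, 50.1% with median-of-ratios scaling, 22.2% without MCAO 3B, 28.7% without sham 5B, 51.6% without sham 9A and 53.4% without MCAO 6B. For 61.8% of genes the 95% interval of the difference excluded a 2-fold change in either direction, and for 94.7% it excluded a 4-fold change; the median standard error was 0.26 on the log2 scale. The call of ENSRNOG00000054459 rests on values of 0: without the 570 tested genes that any library lists at 0, no gene passed (limma, smallest adjusted p = 0.142, 1636 genes at an unadjusted p under 0.05). Leaving out sham 5B lowered the 1673 genes to 1071.

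Relative to all 6 other libraries, the MCAO libraries stood apart in more genes than nearly any other choice of 3. They were the 3 lowest of the 9 in 976 genes and the 3 highest in 415, together 9.24% of the genes tested. The median over the 84 choices of 3 libraries was 245 genes, and 2 of the choices, MCAO included, reached 1391 (exact permutation p = 0.0238, one-sided, and 0.0714 adjusted over the 3 groups, which does not pass). The other such choice was PN 3A, PN 7A and sham 4B, with 1637 genes. PN gave 354 genes (exact permutation p = 0.333) and sham 336 (exact permutation p = 0.357). After median-of-ratios scaling MCAO was lowest in 773 genes and highest in 566, and 3 of the 84 choices reached that total (exact permutation p = 0.0357, and 0.107 adjusted over the 3 groups). The genes lowest in MCAO had a median level of 17.1 FPKM and those highest in MCAO 12.3 FPKM, against 10.4 FPKM for all genes tested. Their median log2 differences from the other 6 libraries were -0.57 and 0.63, against -0.03 for all genes tested. The sign of these differences follows from how the genes were chosen.

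**Figure D2:**
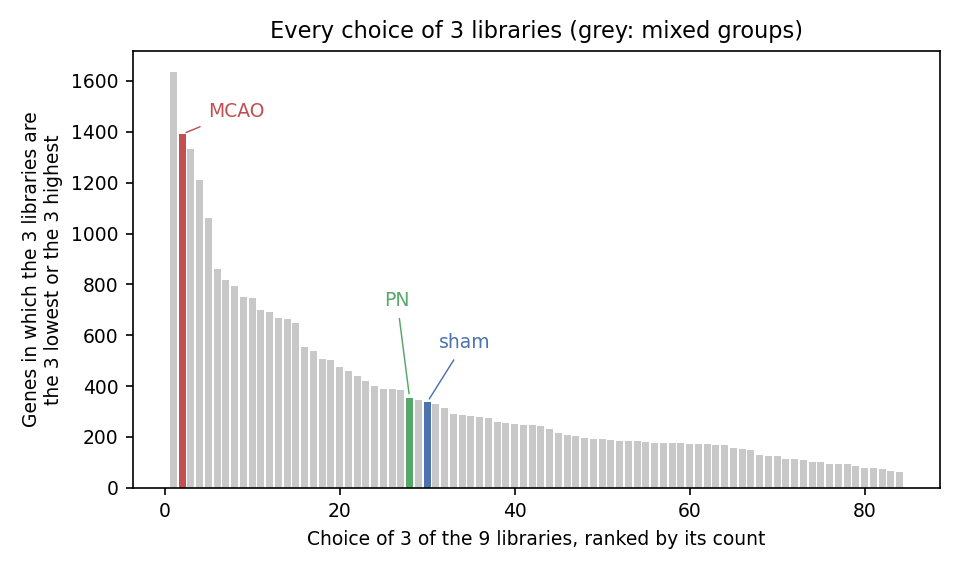
Number of genes (y axis) in which a choice of 3 libraries holds the 3 lowest or the 3 highest of the 9 values, for each of the 84 choices ranked by that number (x axis). The bar of the MCAO group stands second, at 1391 genes, while the counts of PN (354) and sham (336) were reached by 28 and 30 of the choices; mixed choices are drawn in grey.

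PN was compared with MCAO to ask what the treatment changed in rats with the occlusion. The study's design text compares Panax notoginseng with a control group, which was taken here to be untreated MCAO. Of the 15051 genes, 1 rose and none fell. This gene, ENSRNOG00000048608, was at 16.75, 18.05 and 18.72 FPKM in PN 6A, 7A and 3A and was listed at 0 in the 6 other libraries (limma, adjusted p = 2.58e-05). It did not pass with the sample number as a block (limma, adjusted p = 0.134) and passed under every other alternative that kept the gene. ENSRNOG00000028243 showed the same arrangement at a lower level, 2.27 to 3.35 FPKM in the PN libraries and 0 in the others, and missed the threshold (limma, adjusted p = 0.0545), which it passed with no filter on low values (adjusted p = 0.00182) and with array weights (adjusted p = 0.0251) and missed under every other alternative that kept the gene (adjusted p from 0.0520 to 0.528, and 0.470 for array weights with PN 7A left out). ENSRNOG00000056374 was at 9.82 ± 2.58 FPKM in PN (SD, n = 3) against 2.32 ± 0.934 in MCAO (SD, n = 3), a log2 difference of 1.72 with a standard error of 0.26 (limma, adjusted p = 0.1798); it passed with array weights (adjusted p = 0.0251), but not with array weights when PN 7A was left out (adjusted p = 0.601) nor under any other alternative (adjusted p from 0.0884 to 0.641).

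**Figure D3:**
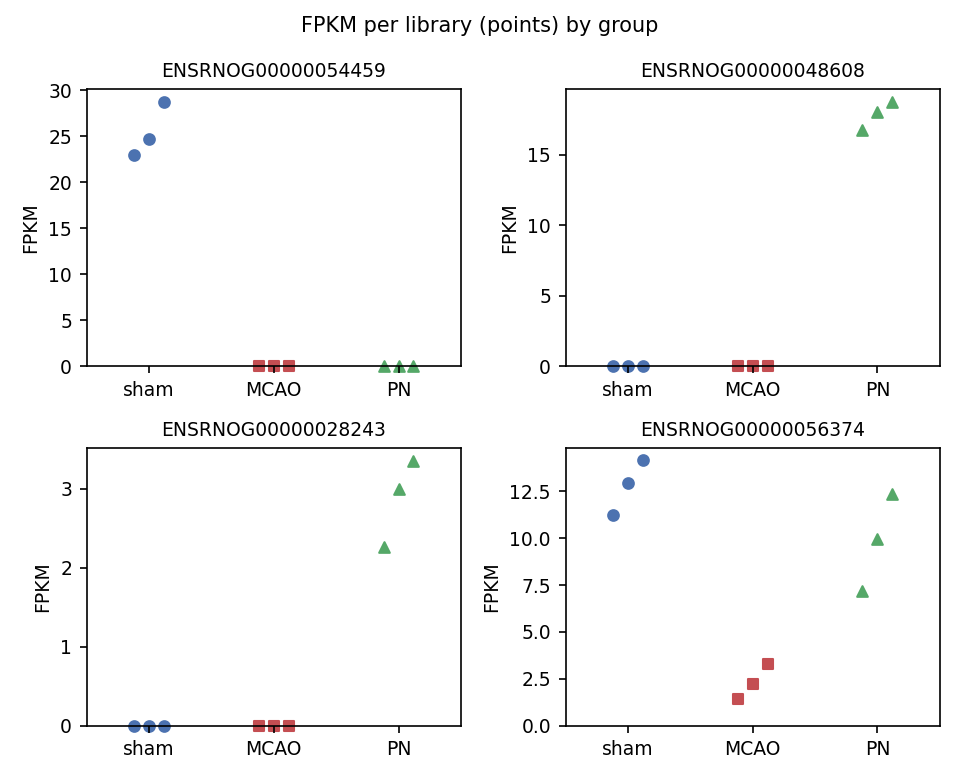
FPKM (y axes, linear from 0) of 4 genes in the sham, MCAO and PN groups (x axes); each point is 1 library, and points within a group are sorted by value. The first 3 genes are listed at 0 in every library of at least 1 group, and ENSRNOG00000056374 is lower in all 3 MCAO libraries than in the other 6.

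As for the occlusion, many small differences between PN and MCAO lay below the adjusted threshold, and chance stays open as their source. At an unadjusted p under 0.05 there were 1994 genes (13.2%), 1314 higher and 680 lower in PN. Other splits of the same libraries, each mixing the groups, gave 103 to 1599 genes. All 3 PN libraries lay above all 3 MCAO libraries in 2050 genes and below them in 1007, together 20.3% where chance gives 10%. This predominance of higher genes shrank or turned under other scalings. As deposited, 65.9% were higher in PN, against 53.2% of 1849 genes with equal sums and 53.9% of 2034 with quantiles. With median-of-ratios scaling the share was 48.6% of 1933. The median log2 difference over all genes was 0.07 as deposited. For 60.7% of genes the 95% interval excluded a 2-fold change in either direction and for 95.1% a 4-fold change.

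Which libraries entered mattered for PN against MCAO. Leaving out PN 3A lowered the 1994 genes at an unadjusted p under 0.05 to 1049, and leaving out MCAO 6B lowered them to 1063. Leaving out PN 6A raised them to 2703, and leaving out any other library gave 1685 to 2016. The column name of PN 3A starts unlike those of the other PN libraries, and what the start marks is not known. With the letter of the sample code as a covariate, A in all PN libraries but in 1 MCAO and 1 sham library, there were 1232. With array weights 377 genes passed the adjusted threshold, 317 higher and 60 lower in PN, with a weight of 6.19 on PN 7A against 0.345 on PN 3A; with PN 7A left out, array weights called 1 gene. Without genes listed at 0 in any library no gene passed (limma, smallest adjusted p = 0.179, 1957 at an unadjusted p under 0.05).

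PN was compared with sham to ask what remained different after treatment. Of the 15051 genes, 2 rose and 1 fell (limma). Those that rose were ENSRNOG00000048608 (adjusted p = 1.29e-05) and ENSRNOG00000028243 (adjusted p = 0.0364), and the one that fell was ENSRNOG00000054459 (adjusted p = 1.12e-05), each listed at 0 in the whole of the lower group. The call of ENSRNOG00000028243 was lost when any 1 of the 9 libraries was left out (limma, adjusted p from 0.0921 to 0.307). ENSRNOG00000056374 was at 9.82 ± 2.58 FPKM in PN and 12.8 ± 1.46 FPKM in sham (SD, n = 3 each), a difference that did not pass (limma, adjusted p = 0.974). At an unadjusted p under 0.05 there were 639 genes, 511 higher and 128 lower in PN, where 753 would be expected by chance, and the groups did not overlap in 8.71% of genes. Of such genes 80.0% were higher in PN as deposited, 69.3% with median-of-ratios scaling and 56.6% without PN 6A, where 313 were higher and 240 lower. Without genes listed at 0 in any library no gene passed (limma, smallest adjusted p = 0.347), and the 639 genes became 254 without sham 5B, 326 with the letter of the sample code as a covariate and 425 among the 11049 genes at 5 FPKM or more in at least 3 libraries, and more than chance gives without PN 7A (782), sham 9A (866) or sham 4B (976) and with array weights (1553).

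Whether PN libraries lay closer to sham than MCAO libraries did was examined from the 2 sets of fold changes. The gene that passed in MCAO against sham was listed at 0 in PN too, so 0 of 1 such genes lay closer to sham in PN. Across the 15051 genes, which are not independent replicates, the log2 fold changes of MCAO against sham and of PN against MCAO had a correlation of -0.65. Both use the same MCAO libraries, which gives a negative value with no effect at all: 100 simulations of unchanged libraries gave a mean of -0.50 (from -0.54 to -0.46). These simulations draw genes independently; over the 840 ways to assign the 9 libraries to the 3 roles the median was -0.51, the lowest value -0.86, and 172 ways gave a value as low as the real one. The covariance was -0.135, against -0.069 in the simulations. With different MCAO libraries for the 2 comparisons the mean of the 6 possible correlations was -0.28, from -0.43 to -0.13. Of the same 840 ways, 52 gave a mean as low (exact permutation p = 0.0619, one-sided). Among the 1673 genes at an unadjusted p under 0.05 in MCAO against sham, 92.5% had the opposite sign in PN against MCAO, where simulated unchanged libraries gave 88.6%.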

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

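Each gene called with the settings of the report was listed at 0 in a whole group, and the counts of calls were 0 to 5 under every alternative run except array weights in PN against MCAO. Leaving out genes listed at 0 in any library, added after the data were seen, gave 0 genes in MCAO against sham, 0 in PN against MCAO and 0 in PN against sham. For MCAO against sham a fit of only the 6 libraries compared called 3 genes, and leaving out 1 library in turn called 1 to 3, in each case with ENSRNOG00000054459 among them. For PN against MCAO no filter on low values called 4 genes, leaving out 1 library in turn called 1 to 4, and array weights called 377, of which 21 are listed at 0 in any library. With the sample number as a replicate block PN against MCAO called 0 genes (smallest adjusted p = 0.134). Whether numbers pair samples cannot be told from 3 pairs. Deviations of same-numbered MCAO and PN libraries from group means correlated at 0.06, -0.40 and -0.16. The block fit of the 6 libraries compared had 1382 genes at an unadjusted p under 0.05, against 1712 unblocked. For PN against sham array weights called 5 genes. The call of ENSRNOG00000028243 in that comparison was lost under 12 alternatives, among them a pseudocount of 0.1 (adjusted p = 0.505), and its adjusted p there was 0.0921 to 0.505. In PN against MCAO it passed only with no filter on low values (0.00182) and with array weights (0.0251). The share of genes at an unadjusted p under 0.05 that were higher in MCAO than in sham crossed the middle with median-of-ratios scaling (50.1%), without MCAO 6B (53.4%) and without sham 9A (51.6%), with a range of 22.2% (without MCAO 3B) to 53.4% over libraries left out in turn, and the share higher in PN than in MCAO did so with median-of-ratios scaling (48.6%); the cause was not tested beyond these settings. The count of genes changed by the occlusion and closer to sham in PN was 1 with quantile normalization, where the gene is ENSRNOG00000054459, listed at 0 in both groups, and 0 to 2 with 1 library left out. The correlation between the 2 sets of fold changes was -0.28 with different MCAO libraries and -0.73 to -0.51 with 1 library left out. All other alternatives fixed beforehand kept the counts of calls within 1.5 times. Genes at an unadjusted p under 0.05 numbered 3300 in PN against MCAO and 1553 in PN against sham with array weights, and 326 in PN against sham with the letter of the sample code as a covariate. The gene list tests fixed beforehand were not run, since no ID could be paired with a gene name. Depth is not known in reads, so what it limits could not be computed. Recovery was simulated with 200 changed genes, none of them at the lowest levels, so the limit with fewer or lower genes was not tested.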

Other observations

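The choice-of-3 counts were planned before their result was seen, as was the test with different MCAO libraries and the tests of the first component; the tests on genes listed at 0, on left-out MCAO libraries and on other splits were chosen after the results were seen.

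The 3 genes that passed in any comparison have the same unusual form, a value in all 3 libraries of 1 group and 0 in the 6 others. Among all genes listed, 60 were at 5 FPKM or more in some libraries and listed at 0 in all the others, in 47 different arrangements of the libraries, and 20 of them were at 0 in 1 library only. Whether scattered zeros fell on whole groups by chance stays open: 8 of the 280 ways to part the libraries into 3 sets of 3, the real groups included, held 3 genes with a value in 1 set alone, but in the real groups these are the same 3 genes that prompted the test. For 3 of the 3 genes a library listing the gene at 0 is deeper than one that has a value. Nearly any arrangement of the libraries would give this, so the check decides little. Depth differed at most 1.33-fold between libraries, far less than the step from 0 to the levels of ENSRNOG00000054459 and ENSRNOG00000048608 where listed. This argues against shallow libraries for these genes. It does not cover ENSRNOG00000028243, which was at a lower level. Also open is whether the authors' assignment of reads to overlapping or near-identical genes differed between groups, whether the animals differed in genotype, or whether the treatment changed these genes; without names, positions and reads these were not tested.

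A second pattern is that the MCAO libraries differ a little from both other groups in many genes. Scaling as its whole source is argued against: median-of-ratios scaling moved the direction of these genes (976 lowest and 415 highest to 773 and 566) but left their number at 1339, from 1391, reached by 3 of 84 choices of 3 libraries. Chance stays open, since 2 of 84 choices reached the number as deposited, and the 5% limit set beforehand did not count that 3 groups were tested (exact permutation p = 0.0714 adjusted over them, and 0.107 after scaling). Open too is whether 1 MCAO library decides: with each left out, the 2 kept were lowest or highest of the 8 in 2035 to 2703 genes, where the median choice of 2 had 831.5 to 966, but 2 or 3 of the 28 choices did as well, over 5%. A mild occlusion effect that is weaker under treatment may be held as a hypothesis only. With different MCAO libraries in the 2 comparisons, the mean correlation was -0.28, so sharing is not the source of that value. The median over the 840 assignments was then -3.57e-05. Still, 52 of the 840 were as negative (exact permutation p = 0.0619, one-sided), over the 5% limit set beforehand. A chance arrangement of the libraries thus stays open. Batches of surgery or dissection that follow the groups cannot be told apart from such an effect with these labels.

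Other splits of each set of 6 libraries are 10 in number, too few for a share under 0.05. For MCAO against sham 5 of the 10 splits called at least the real 1 gene (highest other 2), and 1 of 10, the real one, reached its 1673 genes at an unadjusted p under 0.05 (highest other 1414). For PN against MCAO 4 of the 10 splits called at least 1 gene (highest other 2), and 1 of 10, the real one, reached 1994 (highest other 1599). For PN against sham 1 of 10, the real one, called 3 genes (highest other 2), and 5 of 10 splits reached 639 genes at an unadjusted p under 0.05. The split with 2145 put PN 3A, PN 7A and sham 4B together. It was singled out as the highest after the counts were seen. A structure of the samples other than treatment is possible but was not tested, and chance stays open. The 377 genes that array weights called for PN against MCAO were exceeded by 4 of the 9 other splits of these libraries under the same weighting, of which the highest called 6740. In these 4 the estimation of the weights stopped before it converged, with weights of 8.76 to 31.1 on 1 library, so they are a poor standard. The other mixed splits, where it converged, called 0 to 2 genes. The 377 genes rest on PN 7A, since array weights called 1 gene with it left out.

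The last pattern is the first component, which runs from MCAO 7A to PN 3A and has 36.1% of its variation between groups (68 of 280 partitions as large, exact permutation p = 0.243). Its score rose with the FPKM sum of the library (Pearson r = 0.861 over 9 libraries, permutation p = 0.00269, 0.00807 adjusted over 3 measures). Spearman rho was 0.667 (permutation p = 0.0588, 0.176 adjusted). But r was 0.562 without MCAO 7A and PN 3A, so the relation rests in part on them and stays open. The score and the sum also come from the same unscaled FPKM values, so a relation may be partly built in. The component was not recomputed after scaling. Relative depth did not follow the component (Pearson r = -0.0121, permutation p = 0.9754; Spearman rho = 0.10, permutation p = 0.811; r = -0.413 without MCAO 3B and PN 7A), nor did the share of FPKM in the top 50 genes (Pearson r = 0.102, permutation p = 0.797; Spearman rho = -0.217, permutation p = 0.583; r = -0.263 without MCAO 3B and PN 3A). Differences in the brain region dissected are a candidate explanation that needs gene names and was not tested.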
